A study of Mus musculus with 6 samples.

How the data were processed

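RNA abundance was compared between resting splenic CD4 T cells of C57BL/6J mice treated with vasoactive intestinal peptide (VIP) and untreated cells of the same kind. Per the labels' protocols, spleens of males and females were used, several pooled for each sample, CD4 cells were taken up with magnetic beads, and total RNA was isolated on columns. Labelling with Cy3 and Cy5 started from 250 ng of total RNA, per the labels' protocols. Each of 6 2-colour arrays held 1 VIP-treated and 1 untreated sample, which the labels number as biological replicates 1 to 6. VIP-treated RNA carried Cy5 on replicates 1, 3 and 5 and Cy3 on replicates 2, 4 and 6. The dose and the length of treatment are not given in the sources used here.

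The deposited scanner tables hold spot intensity values from Agilent Feature Extraction 9.5.1.1, with probe coordinates on mm9 (NCBI37), per the file headers. Each array has 45018 features, of which 1639 are controls, and the other 43379 spots carry 41174 probes. The authors also deposited a table of 1 value per spot and array, which matched the scanner tables' log10 ratio of Cy5 over Cy3 with the sign turned on replicates 2, 4 and 6. The largest difference after turning the sign was 4.8e-06, so scale and direction are settled and positive values are higher with VIP. Every array's median in that table is 0, and between 12.5% and 24.2% of the spots are listed at exactly 0. It served only as an alternative.

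Gene names in such files follow the array's design, so they were updated through a RefSeq table by accession without version. This matched 24844 of the 41174 probes (60.3%), and the others kept the name in the files. No genome or exon annotation of the mm9 build was used here, so probe positions are given without exon or UTR. Coordinates count from 1.

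The mean signal minus the median local background was corrected with normexp and an offset of 50, then normalized within each array by loess with limma 3.58.1 in R 4.3.3. Control spots were left out after background correction, and spots the scanner software marked as outliers (1.93% to 8.96% per array) were left out as well. Spots of the same probe were averaged. A probe was kept if it was well above background on at least 3 of the 6 arrays in the channel of either treatment, which held for 29760 probes. It also had to be measured on at least 2 arrays of each dye orientation, a rule chosen after seeing the data, which left 27454. Each gene was represented by its probe of highest mean log2 intensity, giving 19225 genes, of which 5808 had more than 1 kept probe.

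The comparison was a limma linear model on the log2 ratio of VIP-treated over untreated, with a probe-specific dye term and empirical Bayes moderation. Tests were 2-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Because both treatments share an array, the fit is paired within arrays. Pairing rests on the design, which puts both samples of a replicate number on the same array. Values per array with the dye effect removed subtract a dye term fitted on the same arrays. For each gene this makes the means of both dye orientations equal, so these values are not independent readings of each array. Fold values are 2 raised to the log2 ratio, and errors are standard errors of the fitted log2 ratio over 6 arrays unless fewer are named. The number of arrays limits the precision, and with 6 arrays the model has 4 residual degrees of freedom plus 6.55 prior ones.

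In addition, 30 gene lists were tested on the 17171 genes measured on all 6 arrays, with camera at a preset correlation of 0.01. Beside it stand camera with an estimated correlation, and fry (both with Benjamini-Hochberg adjustment over the lists). The lists cover cAMP-responsive, immediate-early, G protein, RGS, naive, activation, T cell receptor, Th1, Th2, Th17, regulatory T cell, chemokine and adhesion, MAP kinase, NF-kappaB, cytokine receptor, apoptosis, cell cycle, interferon-stimulated, stress, ribosomal and glycolysis genes. They also cover markers of B, plasma, macrophage, neutrophil, dendritic, NK, CD8 T, erythroid and platelet cells, which a bead selection from spleen can carry over. The comparison, the lists, the alternatives to the processing and the rule for naming genes were fixed before the data were examined.

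That rule names the 12 largest rises and 12 largest falls among called genes with the same sign on all 6 arrays, leaving out clone, cDNA, predicted and Riken names. It adds the VIP receptors, and from each list up to 4 called members, or the 2 with the lowest p where none was called. A gene named outside it is said to have been chosen after its values were seen. The result of 1 gene under this rule is not reported here.

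Signal over background set the depth. The median Cy3 mean signal ran from 83.6 to 108 and the median Cy5 mean signal from 148 to 235. Between 59.1% and 67.8% of the spots were well above background in Cy3 and between 65.5% and 79.0% in Cy5. Observed against expected log ratios of the spike-in controls had slopes of 0.312 to 0.644, per the file headers. The lowest were 0.472 on replicate 2 and 0.312 on replicate 6, both with VIP in Cy3. Their correlations were 0.828 and 0.597, and 8.96% and 7.95% of their spots were marked. Replicate 4, also with VIP in Cy3, had a slope of 0.644 and a correlation of 0.958. On the VIP-in-Cy5 arrays slopes ran from 0.572 to 0.634 and correlations from 0.916 to 0.957. After the normalization used here, the log2 ratio of Cy5 over Cy3 of spike-in E1A_r60_a22 was 0.588 on replicate 6 and 1.33 on replicate 2. On the other arrays it ran from 1.88 to 2.37. Not every spike-in was closer to equal there, since E1A_r60_n11 stood at -0.683 on replicate 6 and -0.417 on replicate 1. Whether the ratios of genes are compressed in the same way was not tested. The 3 slides held 2 arrays each, a VIP-in-Cy5 array at position 1 and a VIP-in-Cy3 array at position 3. Slide position and dye orientation therefore cannot be told apart. Each slide was also 1 scan, so scan needed no fit of its own beyond that for slide.

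The pipeline was tested on simulated data for the VIP-treated against untreated comparison on 6 arrays, with 19225 genes of which 200 were changed. It called 51 of 67 genes moved by 0.25 on the log2 scale (76.1%), 67 of 67 moved by 0.5 and 66 of 66 moved by 1. Of the 201 calls, 17 were unchanged genes, and no gene was called when none was changed.

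Alternatives covered the scanner software's processed signals, no background subtraction, a normexp offset of 16, median centring, scaling between arrays, quantile normalization of average intensities, the authors' table, and looser and stricter filters on dim probes. Others left out the dye term, used the slide as a block, weighted arrays, left out each replicate, treated the 12 channels as unpaired, used a plain paired t-test, changed the handling of several probes, required a 1.2-fold change, or called at an adjusted p of 0.1. The plain paired t-test also had no dye term. A further 5 alternatives were chosen after seeing the data: marked spots kept, genes measured on at least 1 array of each orientation, genes measured on all 6 arrays, 4 arrays with matched sex-linked transcripts, and the Xist ratio as a covariate.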

Results

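VIP is a neuropeptide that acts on lymphocytes through the receptors Vipr1 and Vipr2, which couple to stimulatory G proteins and raise cyclic AMP (cAMP). The design asked which transcripts of resting mouse splenic CD4 T cells differ between VIP-treated and untreated cells. Transcript abundance was measured on 6 Agilent 2-colour arrays, each with 1 VIP-treated and 1 untreated sample of a biological replicate, so that each treatment has 6 samples. Probes of 60 bases for 19225 genes passed the filters on signal. The number of arrays limits the precision, and the median standard error of a fitted log2 ratio was 0.048.

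With VIP, 594 of the 19225 genes changed, 331 upward and 263 downward. The changes were small. The median size among changed genes was 0.28 on the log2 scale, or 1.21-fold. More than 1.5-fold changes were seen for 23 genes that rose and 9 that fell, and 3 rose more than 2-fold: Syt13, Parp8 and the Riken transcript D330027G24Rik (log2 1.07, named here after its value was seen). The same sign on all 6 arrays was seen for 407 of the changed genes. Changes were called with limma at a Benjamini-Hochberg adjusted p under 0.05, and 3211 genes had an unadjusted p under 0.05. The number of genes changed by VIP was 300 without replicate 1, 254 without replicate 5 and 363 without replicate 6. There were 160 genes higher with VIP without replicate 1 and 151 without replicate 5, and 140, 103 and 142 genes lower with VIP without replicates 1, 5 and 6. The changed genes numbered 38 with the scanner software's processed signals and 4 with the 12 channels treated as unpaired samples.

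Syt13, a synaptotagmin family member, had the largest rise, at 2.33-fold (log2 1.22 ± 0.079 SE, n = 6, adjusted p = 6.04e-05 by limma). Its probe lies on chromosome 2 from 92795818 to 92795877 in mm9. Parp8, a member of the poly-ADP-ribose polymerase family, rose 2.14-fold (± 0.058 SE on the log2 scale, adjusted p = 1.71e-05 by limma), with its probe on chromosome 13 from 117643922 to 117643981. Gpat3, an acyltransferase of glycerolipid synthesis, rose 1.89-fold, and Prkca, which encodes protein kinase C alpha, rose 1.79-fold. The log2 ratio was 0.81 for Khdrbs3, an RNA-binding protein gene, 0.80 for Rundc3b, 0.77 for the microtubule-associated Eml1 and 0.74 for Nudt4, a phosphatase of inositol polyphosphates. It was 0.71 for both Ctla2a, an inhibitor of cysteine proteases, and Fanci, a DNA repair gene of the Fanconi anaemia pathway. Arhgap18, a GTPase-activating protein gene, rose by 0.68 and Sgip1, an endocytosis gene, by 0.66. As the rule for naming requires, each of these 12 genes was higher with VIP on 6 of 6 arrays. Within the 3 slides, Parp8 stood at 1.29, 1.04 and 0.96 and Prkca at 0.98, 0.86 and 0.69 on the log2 scale. A second probe of Syt13 gave 0.01, and second, dimmer probes gave 0.14 for Eml1 and 0.28 for Fanci. Those of Gpat3, Sgip1 and Nudt4 gave 1.05, 0.94 and 0.44.

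Among genes with 1 sign on all 6 arrays, Riken and clone names left aside, Arhgap15 had the largest fall. This GTPase-activating protein gene for Rac fell by 0.82 on the log2 scale (1.76-fold, ± 0.057 SE, n = 6, adjusted p = 6.1e-05 by limma). Its probe lies on chromosome 2 from 44243001 to 44243060, and it stood at -0.81, -0.99 and -0.66 within the 3 slides. Zbtb20, a zinc finger repressor, fell by 0.68, Pdlim4, a cytoskeletal LIM domain gene, by 0.66, Cnga1, a cyclic nucleotide-gated channel gene, by 0.61, and the collagen gene Col11a2 by 0.58. The interferon-inducible genes Ifi203 and Ifi204 of the p200 family fell by 0.53 and 0.52, and Vps13b, a membrane trafficking gene, fell by 0.52. The metalloprotease gene Adamts15 fell by 0.50, with a probe near background that was well above it on 2 of 6 arrays with VIP and 4 untreated, so the size is uncertain. Tnfrsf19, a TNF receptor family member, fell by 0.49, the nucleoside transporter gene Slc28a2 by 0.46 and Arhgap29 by 0.44. By the same rule, each of these 12 genes was lower with VIP on 6 of 6 arrays. A second, dimmer probe of Col11a2 (mean log2 intensity 6.73 against 9.72) gave -0.03, and the other probes of Vps13b gave -0.27 and 0.11. Other probes of Arhgap15, Zbtb20, Pdlim4, Ifi203, Ifi204 and Arhgap29 ran from -0.55 for Arhgap15 to -0.23 for Arhgap29. Adamts15 was not called without replicate 1 (adjusted p = 0.0566), replicate 2 (0.0521) or replicate 6 (0.0547). Of all 24 genes named for their rises and falls, 13 were called from the scanner software's processed signals, 21 without a dye term and 4 in the unpaired fit.

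**Figure D1:**
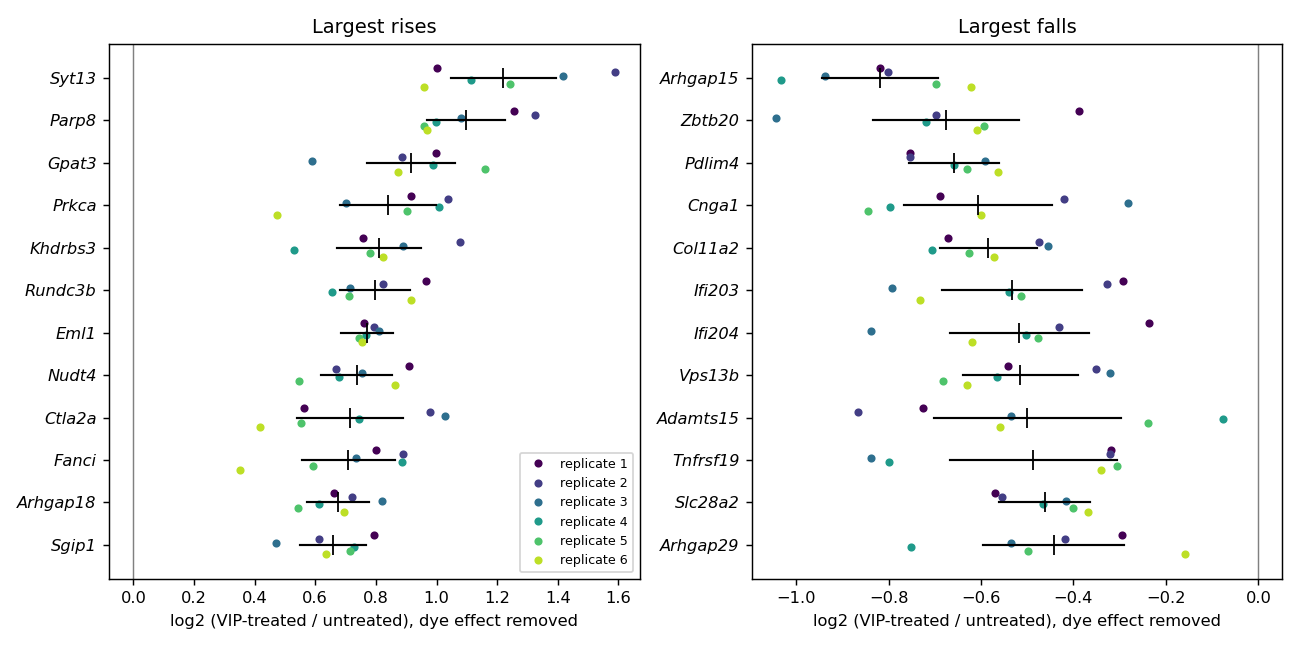
The 12 largest rises (left) and the 12 largest falls (right) among called genes with 1 sign on all 6 arrays, Riken and clone names left out, as log2 of VIP-treated over untreated with the dye effect removed. Dots are the 6 replicates, ticks the fitted values and bars their 95% confidence intervals, running from 1.22 for Syt13 to -0.82 for Arhgap15.

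Of the receptors, Vipr1 was measured well above background in both treatments on 6 of 6 arrays and stood at log2 -0.02 (95% interval -0.12 to 0.08, adjusted p = 0.891 by limma). Its sign turned to 0.0065 without replicate 1 and 0.0016 without replicate 6. For Vipr2, 1 probe was well above background on 1 of 6 arrays with VIP and 0 untreated, and the other probe on 0 of either, so Vipr2 was not tested. The list of VIP receptor and G protein signalling genes had 2 members of 25 that rose and 2 that fell (4 and 3 adjusted over the list alone). Ramp3, a receptor activity-modifying protein gene, rose by 0.41, and Arrb1, which encodes beta-arrestin, rose by 0.28. Adcy7, an adenylyl cyclase gene, fell by 0.42 and Rapgef6, an exchange factor for Rap, fell by 0.35. Ramp3 was not called without replicate 1, 2, 3, 4 or 5 (adjusted p from 0.0516 to 0.119). The list as a whole was not called (adjusted p = 0.708 by camera), with a median of -0.0022, a mean of 0.0035 and a test that pointed upward. None of the 10 regulators of G protein signalling passed by limma over all genes (3 had an unadjusted p under 0.05), and 2 rose adjusted over the list alone, Rgs2 at 0.24 (adjusted p over all genes = 0.0985) and Rgs1 at 0.18 (0.0716). Rgs2 was measured on 5 arrays, and with the slide as a fixed block, where another of its probes stands for the gene, it reached 0.33 with an adjusted p of 0.0133.

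Genes known to respond to cAMP were higher with VIP as a list by camera with a preset correlation (adjusted p = 0.00200). The call was lost by camera (adjusted p = 0.687 with an estimated correlation) and by fry (0.298). Of 27 tested members 3 rose and none fell, 12 rose adjusted over the list alone, and 23 had a positive fitted value with a median of 0.10. Camera used the 19 members measured on all 6 arrays, whose median was 0.071. The kinase gene Sik1 rose by 0.37, the transcription factor gene Atf3 by 0.31 and the phosphodiesterase gene Pde7a by 0.23. Before the dye effect was removed, Sik1 was higher on only 3 of 6 arrays, those with VIP in Cy3. The orphan nuclear receptor genes Nr4a2 (5 arrays) and Nr4a3 stood at 0.35 and 0.26 and Crem (4 arrays) at 0.24. Their adjusted p over all genes by limma was 0.159, 0.117 and 0.199 (these 3 were chosen after their values were seen). The list's median within the 3 slides was 0.09, 0.06 and 0.18, and of the 6 arrays only replicate 3 had a negative list median (-0.03). Sik1 and Atf3 were not called without replicate 1, 4, 5 or 6 (adjusted p from 0.0660 to 0.106 for Sik1 and from 0.101 to 0.132 for Atf3), and Pde7a was not called without any 1 of the 6 replicates (adjusted p up to 0.115) nor with the mean of its probes (0.195), its other probe being at 0.10.

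Among the immediate-early genes, the zinc finger transcription factor genes Egr2 and Egr3 fell, by 0.72 (± 0.12 SE, adjusted p = 0.0107 by limma) and 0.82 (± 0.16 SE, adjusted p = 0.0244 by limma). None of the 18 tested members rose, and adjusted over the list alone 2 rose (Fos at 0.35 and Fosb at 0.27, named here after their values were seen) and 6 fell. The median of the list was -0.08. Both Egr genes were lower on each slide, with Egr2 at -0.49, -1.23 and -0.44 and Egr3 at -0.49, -1.55 and -0.41. A second, dimmer probe of Egr3 (mean log2 intensity 6.69 against 9.63) gave -0.12. The list was lower by camera with a preset correlation (adjusted p = 0.0439), with an adjusted p = 0.687 with an estimated correlation and 0.0676 with the slide as a fixed block. The list was not called without replicate 2 (adjusted p = 0.122), replicate 3 (0.286) or replicate 4 (0.181), and Egr3 not without replicate 2 (0.0631) or replicate 4 (0.0594), nor with the slide as a fixed block (0.0508).

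Markers of the naive, resting T cell changed in both directions. Il7r, the interleukin-7 receptor gene of naive and memory cells, fell by 0.63 (1.55-fold, n = 5 arrays) and Actn1 fell by 0.24, while Ccr7, the chemokine receptor gene of lymph node homing, rose by 0.29. Of 20 tested, 1 rose and 3 fell, and adjusted over the list alone 1 rose and 6 fell. The list as a whole was not called (adjusted p = 0.303 by camera, median -0.06). Camera used only the 13 members measured on all 6 arrays, which leaves out Il7r, while the median is over all 20. Ccr7 was not called without replicate 1, 3, 5 or 6 (adjusted p from 0.0689 to 0.101), and Actn1 not without replicate 1 (0.0532).

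Of 29 T cell activation genes only Tnfsf11, the gene of the cytokine RANKL, changed. It rose 1.97-fold (log2 0.98 ± 0.15 SE, n = 6, adjusted p = 0.00705 by limma) and was higher on 5 of 6 arrays before the dye effect was removed. After removal it was higher on all 6, which the fitted dye term partly builds in. A second probe gave 0.67. The count adjusted over the list alone was also 1. Of 15 Th1 genes, Il12rb2, an interleukin-12 receptor chain gene, rose by 0.23 (2 rose and 1 fell adjusted over the list alone). Of 12 Th2 genes, Il4ra, the interleukin-4 receptor gene, rose by 0.41 (1 rose adjusted over the list alone). None of the 10 Th17 genes or the 13 regulatory T cell genes passed by limma, over all genes or adjusted over the list alone, and 1 and 0 had an unadjusted p under 0.05. Their lowest unadjusted p belonged to Il22 (0.16) and Ccr6 (-0.09), and to Nt5e (0.11, 5 arrays) and Gpr83 (0.10), given here as log2 values. None of these lists shifted as a whole by camera (adjusted p = 0.107 for activation, 0.351 for Th1, 0.107 for Th2, 0.849 for Th17 and 0.373 for regulatory T cells). Il12rb2 was not called without replicate 1, 4, 5 or 6 (adjusted p from 0.0562 to 0.0993).

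Of 30 MAP kinase pathway genes, Dusp10 and Dusp6, phosphatases that switch off MAP kinases, rose by 0.51 and 0.41 and the related Dusp16 fell by 0.31 (3 rose and 1 fell adjusted over the list alone). Before the dye effect was removed, Dusp6 was higher on 4 of 6 arrays. Of 29 T cell receptor signalling genes, Ptpn22, a phosphatase that dampens receptor signalling, rose by 0.51 and Dgkz, a diacylglycerol kinase gene, fell by 0.17 (1 rose and 5 fell adjusted over the list alone). None of 20 NF-kappaB genes passed by limma over all genes (6 had an unadjusted p under 0.05), and 1 rose and 1 fell adjusted over the list alone. These were Tnfaip3 at 0.24 (4 arrays, adjusted p over all genes = 0.0704) and Nfkbia, the gene of the inhibitor IkappaB alpha, at -0.31 (0.0562, or 0.0271 with the slide as a fixed block). Il6ra, the interleukin-6 receptor gene, fell by 0.32 as the 1 changed gene of 25 cytokine receptor and JAK-STAT genes, and Itga6, an integrin gene, fell by 0.33 as the 1 changed gene of 22 chemokine receptor and adhesion genes, with the same counts adjusted over the list alone. None of these lists shifted as a whole by camera (adjusted p = 0.107, 0.590, 0.780, 0.536 and 0.478 in the order named). The median of the NF-kappaB list was 0.0012 and its mean -0.0080, with a test that pointed downward. Other probes of Dusp16 gave -0.13 and -0.06, and with the mean of its probes it was not called (adjusted p = 0.125). Dgkz was not called without any 1 of the 6 replicates (adjusted p from 0.0881 to 0.179) nor with the slide as a fixed block (0.0715).

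Genes of glycolysis and glucose use were higher as a list by camera with a preset correlation (adjusted p = 0.00886). That call was lost by camera (adjusted p = 0.687 with an estimated correlation) and by fry (0.252). Of 19 tested, Slc16a3, the lactate exporter gene, rose by 0.55 (1.47-fold, adjusted p = 0.000195 by limma) and the growth factor gene Vegfa by 0.25, while Pdk1, which restrains pyruvate oxidation, fell by 0.28. Adjusted over the list alone 5 rose, among them Gapdh (0.16), Tpi1 (0.15) and Hif1a (0.23), which were named after their values were seen, and 1 fell. The median was 0.07 over all arrays and 0.03, 0.11 and 0.08 within the 3 slides, and of the 6 arrays only replicate 2 had a negative one (-0.02). It was 0.029 on the 4 arrays with matched sex-linked transcripts. Vegfa was not called without replicate 1 (adjusted p = 0.0580) or 5 (0.0689), and Pdk1 not without replicate 1, 4, 5 or 6 (0.0520 to 0.101).

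Of 28 apoptosis and survival genes, Bcl2l11, the gene of the pro-apoptotic protein Bim, rose by 0.29 and the TNF receptor gene Tnfrsf1b by 0.23, and the pro-survival gene Bcl2 fell by 0.22 (5 arrays). Adjusted over the list alone 6 rose and 3 fell, and the list was not called (adjusted p = 0.0829 by camera). Of 22 heat shock and stress genes Xbp1, a transcription factor gene of the unfolded protein response, rose by 0.31 (2 rose adjusted over the list alone). That list was not called (adjusted p = 0.536 by camera), with a median of -0.01 against a mean of 0.01 and a test that pointed upward. None of 33 cell cycle genes passed by limma, over all genes or adjusted over the list alone (4 had an unadjusted p under 0.05), with Mcm4 at 0.14 and Mcm7 at -0.11, and the list was not called (adjusted p = 0.918 by camera). Tnfrsf1b was not called without replicate 1, 4, 5 or 6 (adjusted p from 0.0938 to 0.144). Bcl2 was not called without replicate 1, 3, 4, 5 or 6 (0.0949 to 0.158), nor with the slide as a fixed block, where another probe stands for the gene at -0.15 (0.270), nor with the mean of its probes (0.142).

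No ribosomal protein gene passed by limma among 33, over all genes or adjusted over the list alone (6 had an unadjusted p under 0.05), with Rps24 at -0.25 and Rpl19 at -0.17, and the list median was -0.07, or -0.035 without replicate 1, -0.11 without replicate 4 and -0.13 with median centring. The list was lower by camera with a preset correlation (adjusted p = 0.0373), with an adjusted p = 0.687 with an estimated correlation and 0.456 without a dye term. Within the 3 slides the median was -0.12, 0.07 and -0.11, so its direction did not hold on slide 2. These genes carry a large dye effect, with a median of 0.73 in favour of Cy5. The list was not called without replicate 1 (adjusted p = 0.231), replicate 2 (0.158), replicate 5 (0.0528) or replicate 6 (0.333).

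Interferon-stimulated genes were lower as a list by camera with a preset correlation (adjusted p = 0.000402). This call was lost by camera (adjusted p = 0.687 with an estimated correlation) and by fry (0.408). None of the 27 tested members had a positive fitted value, and the median was -0.12, or -0.068 with median centring and -0.079 with the Xist ratio as a covariate. Ifit2, an antiviral effector gene, fell by 0.21 as the 1 changed gene, over all genes and adjusted over the list alone. The median was -0.02, -0.27 and -0.07 within the 3 slides. On single arrays it was 0.07 on replicate 1, -0.0048 on replicate 5, -0.41 on replicate 3 and -0.14 to -0.10 on the other 3. Macrophage and monocyte markers had a median of -0.23 on replicate 3 and -0.13 on replicate 4, and CD8 T cell markers 0.27 on replicate 3. Without replicate 3 the median was -0.04 and the list was not called (adjusted p = 0.170), and Ifit2 was not called without any 1 of the 6 replicates (0.0518 to 0.102) nor with the mean of its probes (0.130).

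**Figure D2:**
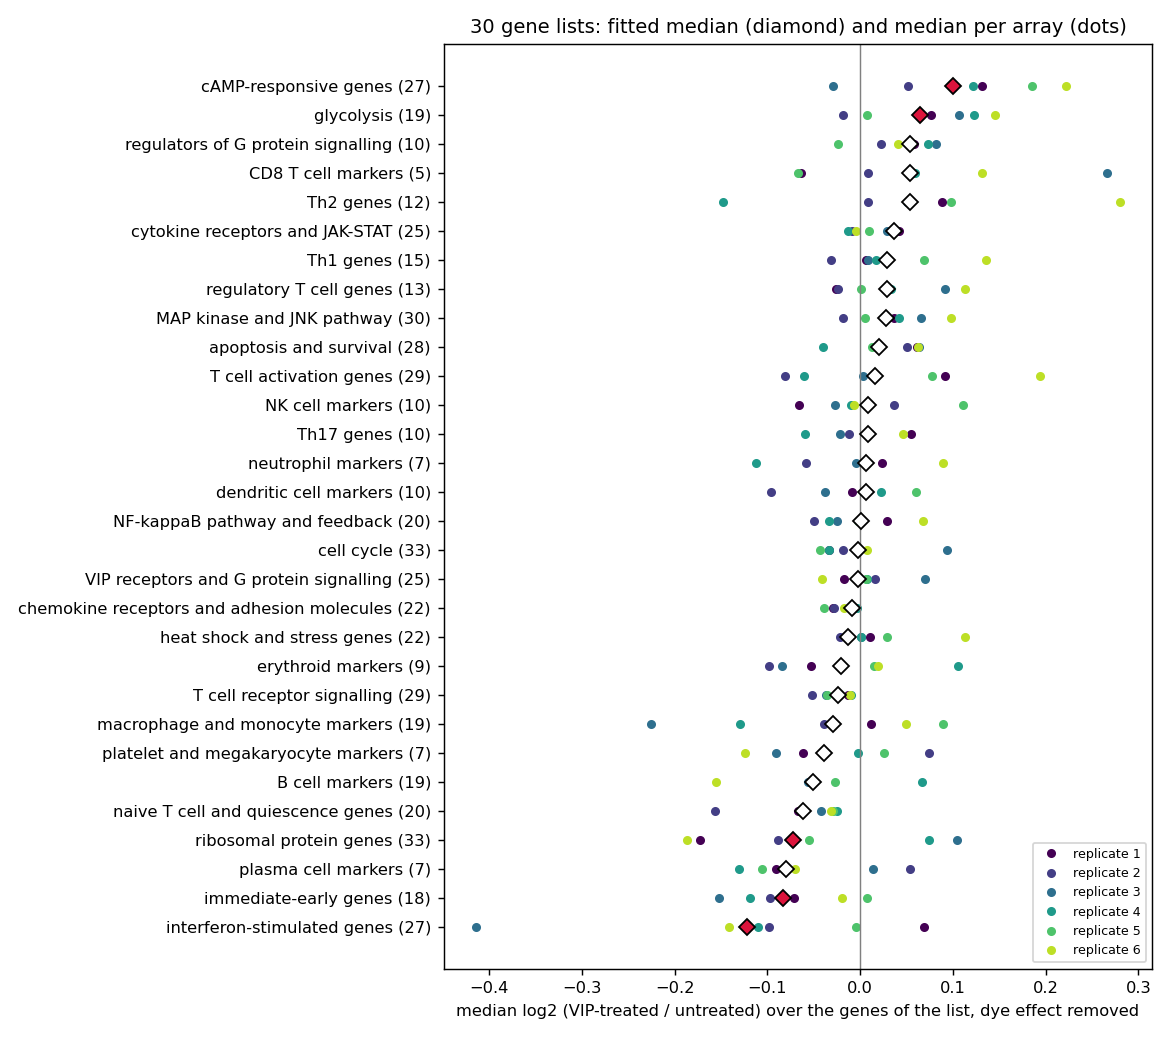
Median log2 of VIP-treated over untreated for each of 30 gene lists with the dye effect removed. Diamonds are the fitted medians, red where camera with a preset correlation gave an adjusted p under 0.05, dots the medians on the 6 arrays, and the number of tested genes follows each name. The 5 red lists run from -0.12 for interferon-stimulated genes to 0.10 for cAMP-responsive genes.

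**Figure D3:**
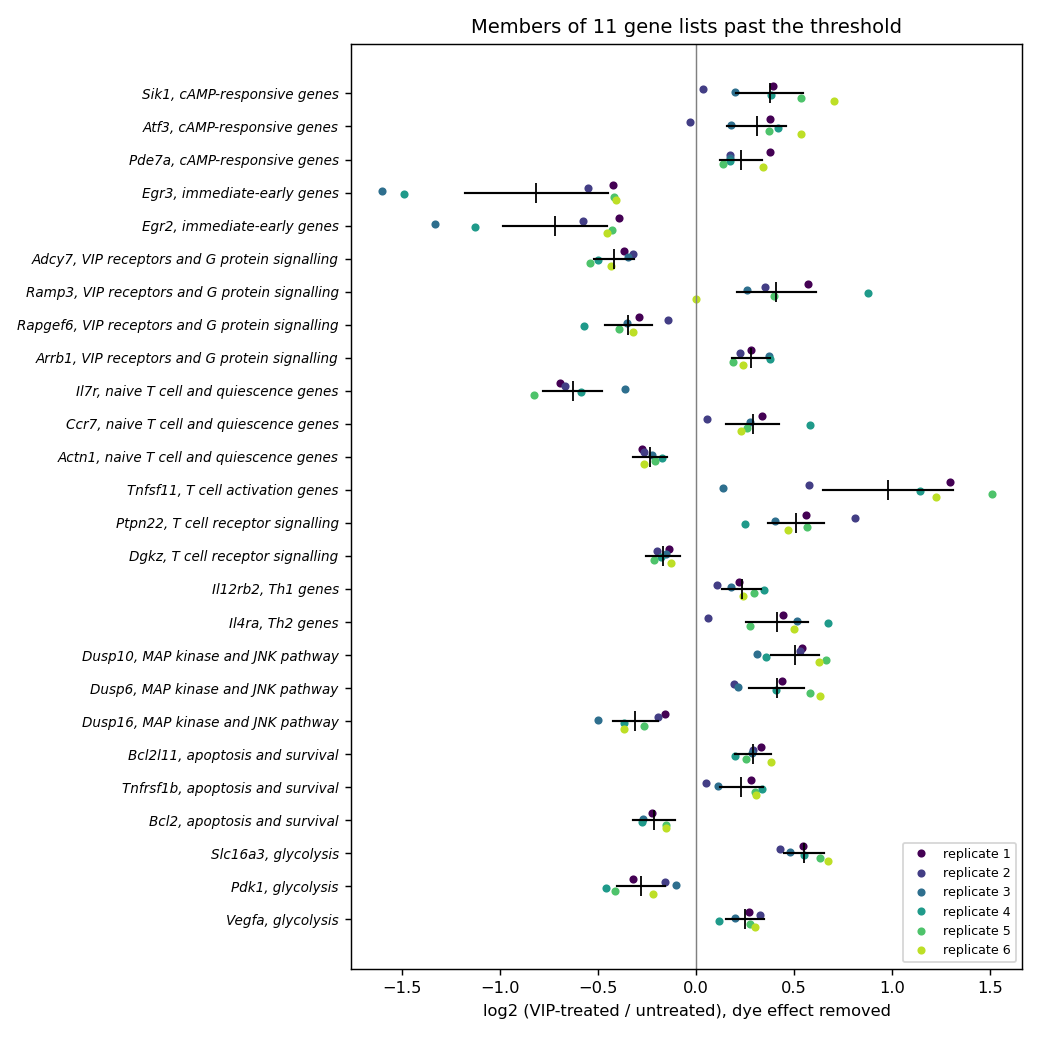
Named members of 11 gene lists that passed the test over all genes, as log2 of VIP-treated over untreated with the dye effect removed. Dots are the replicates, ticks the fitted values and bars their 95% confidence intervals, from 0.98 for Tnfsf11 to -0.82 for Egr3.

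Markers of other cell types that a CD4 bead selection from spleen can carry over did not pass, apart from 1 erythroid gene. None of 19 B cell, 7 plasma cell, 19 macrophage, 7 neutrophil, 10 dendritic cell, 10 NK cell, 5 CD8 T cell or 7 platelet markers passed by limma, over all genes or adjusted over the list alone, and 6 of these 84 had an unadjusted p under 0.05. The members with the lowest unadjusted p stood at -0.10 for Cd79b and -0.09 for Bank1 (B cells, with another Bank1 probe at 0.03), -0.18 for Jchain and -0.11 for Mzb1 (plasma cells), and 0.18 for Cd14 and -0.11 for Hmox1 (macrophages). They stood at -0.08 for Cxcr2 and 0.13 for S100a8 (neutrophils), 0.14 for Runx2 and 0.11 for Clec10a (dendritic cells), and 0.07 for Prf1 and -0.08 for Klrb1c (NK cells). Within the 3 slides the sign was not constant for S100a8 (0.08, -0.13 and 0.44) or Clec10a (-0.13, 0.15 and 0.33). The CD8 T cell genes Cd8b1 and Gzmk were at 0.13 and 0.09, and the platelet genes Itga2b and Gp5 at -0.12 and 0.07. Gzmk turned to -0.011 without replicate 3 and to -0.040 on the 4 arrays with matched sex-linked transcripts. Of 9 erythroid markers Car2, a carbonic anhydrase gene, rose by 0.22 (1 adjusted over the list alone), but was not called without replicate 1, 3, 4, 5 or 6 (adjusted p from 0.0617 to 0.118). The erythroid list had a median of -0.02, a mean of -0.0043 and a test that pointed upward, and the NK list a median of 0.0091, a mean of -0.0010 and a test that pointed upward. None of the 9 lists was called by camera (adjusted p from 0.0829 for plasma cells to 0.849 for NK cells). Of the 30 lists 0 were called by camera with an estimated correlation (0 at an unadjusted p under 0.05) and 0 by fry (4 at an unadjusted p under 0.05), against 5 by camera with a preset correlation (8 without replicate 4), while 15 passed fry's test for change in either direction.

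The treatments were not matched in sex-linked transcripts, chosen after their values were seen, on 2 arrays. Xist, the transcript of the inactive X chromosome, stood at -6.12 on replicate 3 and 2.03 on replicate 6, against -0.08 to 0.34 on the other 4. The median of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty was 1.45 on replicate 3 and -2.72 on replicate 6, against -0.05 to 0.03 on the others. Some samples showed transcripts of 1 sex alone. Xist was near background on replicate 4 in both treatments (log2 intensity 6.21 with VIP and 6.29 untreated) and in the VIP-treated sample of replicate 3 (6.34), and on replicate 5 Ddx3y (5.89 and 5.75) and Eif2s3y (5.98 and 6.00) were near background in both. With the 4 matched arrays alone, an alternative chosen after seeing the data, 369 genes were called, 302 of them among the 594, and of the 24 genes named for their rises and falls 23 were called, Adamts15 being the exception. Of the 32 list members called outside those 24, 19 were called on the 4 matched arrays. Those not called there were Atf3, Pde7a, Ccr7, Actn1, Dgkz, Il12rb2, Il4ra (adjusted p = 0.0889), Dusp16, Tnfrsf1b, Bcl2, Ifit2, Vegfa and Car2. By camera with a preset correlation, the cAMP list then had an adjusted p = 3.93e-08, the ribosomal list 0.0203, the glycolysis list 0.0502, the immediate-early list 0.108 and the interferon list 0.463. An estimated correlation was not run on these 4 arrays, and over all 6 the adjusted p = 0.687 with an estimated correlation for each of these lists.

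**Figure D4:**
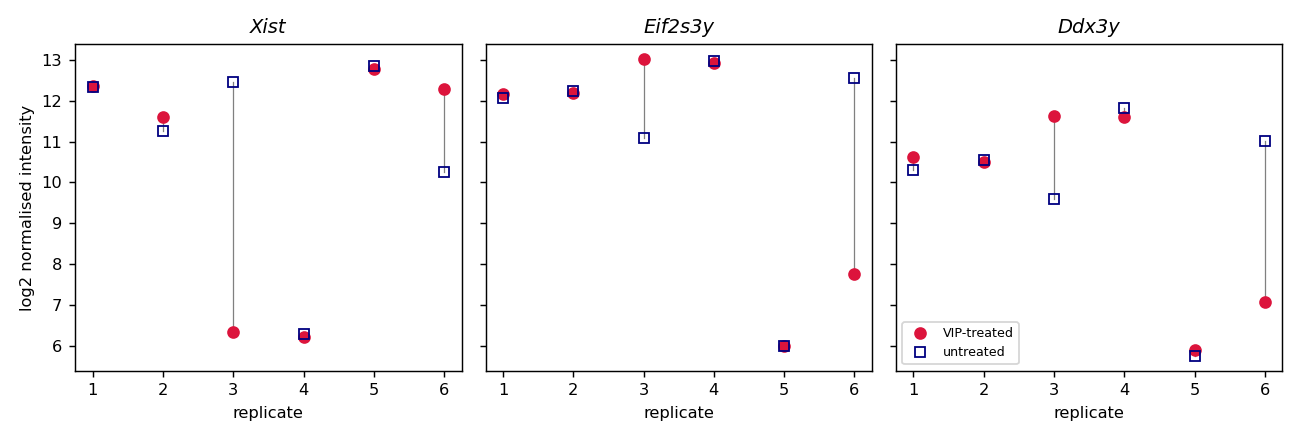
Normalized log2 intensity of Xist and the Y-linked genes Eif2s3y and Ddx3y in the VIP-treated and untreated sample of each replicate, with a grey line between both. The pairs lie apart on replicates 3 and 6, where the log2 ratio of Xist was -6.12 and 2.03.

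The dye itself changed the signal of more genes than VIP did, since 3023 genes had a dye effect, 1503 brighter in Cy5 and 1520 brighter in Cy3, including 143 of the 594 genes changed by VIP. Before this effect was removed, log2 ratios of VIP-treated over untreated correlated at 0.376 to 0.729 between arrays of the same dye orientation and at -0.278 to -0.119 between arrays of opposite orientation, across genes, which are not independent replicates. Without a dye term 125 genes were called. With the slide as a fixed block 604 genes changed, 489 of them among the 594. Of the 32 list members called as changed outside those 24, Slc16a3 alone was called from the scanner software's processed signals, 7 were called without a dye term and 0 in the unpaired fit.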

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

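The search for single arrays far from the others was fixed before the data were examined, and no test of an explanation was run for the values it found. The median of the naive T cell and quiescence genes was -0.16 (log2, dye effect removed) on replicate 2, below the other 5 arrays at -0.067 to -0.025. The median of the cell cycle genes was 0.094 on replicate 3, above the other 5 arrays at -0.043 to 0.0076. Of the 115 values examined these 2 stood apart. A rate of 1 in 20 would give 5.75, but it does not hold here. Genes not measured on all 6 arrays were counted and could not be marked, and removing the dye effect makes the values of the arrays depend on each other.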

How the results depend on the processing

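The alternatives with marked spots kept, with genes measured on all 6 arrays or on at least 1 array per orientation, with the 4 arrays of matched sex-linked transcripts, and with Xist as a covariate were chosen after seeing the data. Of the values recomputed for named genes and for the 5 called lists, 2138 stayed on the same side of the threshold in the same direction, 423 were no longer called, 18 became called and 4 turned sign. The median of all genes stayed within 0.1 of 0 on the log2 scale in every setting. This is no check on the results, since each scaling centres the log ratios of an array beforehand. The numbers of genes changed by VIP (594), genes higher with VIP (331) and genes lower with VIP (263) became 38, 29 and 9 with processed signals, 41, 31 and 10 with the authors' table, 313, 212 and 101 with median centring, and 125, 88 and 37 without a dye term. They became 4, 3 and 1 with 12 unpaired channels, 22, 18 and 4 when a 1.2-fold change was required, and 1071, 554 and 517 at an adjusted p of 0.1. A plain paired test, which had neither a dye term nor moderation, gave 1, 1 and 0, with 1819 genes at an unadjusted p under 0.05. Array weights gave 917 changed and 430 lower. An offset of 16 gave 371 changed and 149 lower, marked spots kept gave 148 lower, and the 4 matched arrays gave 369 changed and 141 lower. The requirement of a minimum fold and the looser threshold change the counts by construction, and the 4 arrays hold fewer samples; for the others the cause was not tested. Leaving out 1 replicate gave 254 (replicate 5) to 494 (replicate 4) changed, with 300 without replicate 1 and 363 without replicate 6, 151 to 276 higher and 103 to 218 lower, on fewer arrays.

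The count of 5 called gene lists was 3 with no background subtraction, an offset of 16, the authors' table, the stricter filter, no dye term and the 4 matched arrays, and 8 on genes measured on all 6 arrays and without replicate 4. It was 0 by camera with an estimated correlation and 0 by fry, with 0 and 4 at an unadjusted p under 0.05. Without single replicates it ran from 4 to 8. Of 25 alternatives for each list, the call was kept in 23 for cAMP, 22 for glycolysis, 21 for interferon-stimulated, 13 for ribosomal and 9 for immediate-early genes. The cause was not tested. Vipr1 (-0.02) ran from -0.041 without replicate 2 to 0.0065 without replicate 1, and stood at 0.0016 without replicate 6. Gzmk (0.09) ran from -0.011 without replicate 3 to 0.15 without replicate 5 and stood at -0.040 on the 4 matched arrays. Lists were not run with unpaired channels, the plain paired test, other handling of several probes or the slide as a random block, where the consensus correlation was 0.0191. Signal over background limits what can be said of dim transcripts such as Vipr2.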

Other observations

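The tests of other splits of the arrays and of replicate 3 in the interferon list were set before their results were seen, and those of second probes, spike-in controls, sex-linked transcripts and estimated correlation were chosen only after. The genes in the next paragraphs were also chosen after their values were seen.

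Of 52 histone gene names tested, a group put together after the values were seen and not tested for enrichment, 9 rose and 0 fell by limma, against 331 that rose of all 19225 genes. Old and current names of 1 gene can both be among them, such as Hist1h1e (-0.04) beside H1f4 (0.28), so they are not all separate genes. A positive fitted value was found for 42, and the median was 0.085. The largest rises were H2bc4 at 0.45 and H2bu2 at 0.41, and Cenpa, the centromeric histone gene, rose by 0.32. The count that rose was 4 without replicate 2, 5 without replicate 5 and 5 without replicate 6. It was 0 with processed signals and 0 with the authors' table, where 41 fitted values were positive. Of the p200 family of interferon-inducible genes, 3 of 6 fell, Ifi203, Ifi204 and Ifi211 (-0.45, 5 arrays), and the other 3 did not pass. Ifi211 was not called without replicate 4 (adjusted p = 0.0753) or 6 (0.0503), and none of the 3 was called with processed signals or the authors' table.

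The multidrug transporter genes Abcb1b and Abcb4 rose by 0.64 and 0.37, and Abcb1a, which lies beside them on chromosome 5, by 0.26. Abcb1a was not called without replicate 1, 3, 4 or 6 (adjusted p from 0.0562 to 0.0770). Rapgef3, the gene of the cAMP-binding exchange factor Epac, rose by 0.47 (1.38-fold, adjusted p = 0.000591 by limma), and Prkce, a protein kinase C gene, by 0.43, while Prkd2 fell by 0.32. Of the inositol trisphosphate receptor genes, Itpr2 fell by 0.36 and Itpr1 (5 arrays) rose by 0.28, the rise not called without replicate 1, 2, 5 or 6 (adjusted p from 0.0564 to 0.142). The transcription factor genes Myb and Epas1 both rose by 0.58. The checkpoint receptor gene Vsir fell by 0.38. All of these genes kept their direction under each of 5 scalings, which says little. Quantile normalization of average intensities leaves log ratios as they are, and scaling between arrays only multiplies those of each array by a positive factor. With processed signals only Abcb1b (adjusted p = 0.0185 by limma) and Rapgef3 (0.0431) were called, and the others had an adjusted p from 0.0691 (Abcb4) to 0.192 (Itpr1). With the authors' table the same 2 genes alone were called. That table holds the scanner software's own log ratios, so it is not a separate check.

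The 594 genes called as changed (300, 254 and 363 without replicates 1, 5 and 6) rest on arrays where dye orientation and slide position go together. A dye bias of single probes is argued against by second probes of called genes, which went the same way for 225 of 244 genes (92.2%, exact 95% interval 88.1% to 95.2%), against 61.9% for the dye term of genes with a dye effect, and the sex-linked mismatch as the whole cause by 302 genes called again on replicates 1, 2, 4 and 5. With 10 splits of the arrays too few for a share under 0.05, the real one gave 594, 331 higher and 263 lower against at most 0 in the others (1 of 10 each), and 5 lists (8 without replicate 4) against at most 8 (4 of 10). A dye bias shared by all probes of a transcript that differs between slide positions stays open, since no array holds the other orientation at either position. A shift of the whole scale was not decided by 10 spike-in controls. The median size of their VIP term was 0.073 (largest 0.32), no larger than their errors (SE from 0.078 to 0.18). Called genes went both ways, 331 higher and 263 lower. These counts cannot decide on such a shift either, since loess centres the log ratios of each array before the test. The VIP term had the sign of the dye term on 10 of 10 spike-ins and on 307 of the 594 called genes. These shares cannot be compared, since spike-ins have expected log ratios of their own, which their dye term also holds.

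Xist and the Y-linked genes differed between the samples of replicates 3 and 6. An effect of VIP is argued against by Xist at 2.03 on replicate 6 and -6.12 on replicate 3. An exchange of RNA between these replicates is argued against because 1 pair would still differ by -3.92. Spleens of different sex in the VIP-treated and untreated pools are consistent with the median of the Y-linked genes, which was -2.72 on replicate 6 and 1.45 on replicate 3, opposite to Xist on both. A wrong label or a sample from outside the series was not tested.

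Interferon-stimulated genes were lower with VIP as a list. Their shift is compatible with a difference on replicate 3 alone, since the adjusted p by camera was 0.170 without it. Co-variation of the list's genes between samples stays open, with an estimated correlation of 0.585. The adjusted p = 0.687 by camera with that correlation cannot decide it. The T cell receptor list, with an estimated correlation of -0.012, had the same adjusted p. Over the other alternatives run, the adjusted p by camera ran from 8.13e-09 without replicate 1 to 0.463 on the 4 arrays with matched sex-linked transcripts. An effect of VIP on these genes stays open, with a median of -0.041 without replicate 3 and -0.025 on those 4 arrays.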
